A study of Mus musculus with 20 samples.

How the data were processed

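Total RNA of dorsal epidermis, separated with dispase, was hybridised as biotin-labelled cRNA to Affymetrix Gene ST arrays, per the labels' protocols. The deposited values are probe-set intensity on a linear scale, made by the authors with Affymetrix Expression Console and PLIER (a probe-level model that summarises the probes of a probe set), per the submitters' processing notes; versions are not given in the sources used here. The table has 35556 probe sets and 20 arrays, with values from 0.000106 to 49782 and no missing value. PLIER values near 0 are noisy on a log scale, so a fold change is on the log2(value + 16) scale and understates the change of dim probe sets. The 75th percentiles of the arrays lay between 9.01 and 9.18 on this scale, within the 0.5 set before the data were examined as the limit for using the values as deposited. Arrays give no count depth: their number limits the precision.

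Groups, sex and day were taken from the labels. There were 12 arrays labelled male and 8 labelled female, and 10 per genotype. Sex and experiment coincide: the imiquimod day 4 mice are all labelled female and the others male.

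The probe table of the platform lists 23410 of the IDs, 21789 with 1 symbol and 1621 with several, and 12146 probe sets are unnamed here. Before any name was used the pairing of IDs and values was checked. Of 656 sets of IDs with 1 list of accessions, 0 had identical values, while 225 groups of probe sets (701 in all) had identical values on all arrays and 4 of these groups held a repeated symbol. The levels of ribosomal protein and olfactory receptor labels, given in the report, did not differ as those gene classes do. No gene is therefore named. Planned analyses that need names were not run: the level of Grhl3, the fixed gene lists, the cell type markers, the rule for named genes and the mean over probe sets of a gene. The rule for named genes was to name the largest changes among called genes whose arrays do not overlap; in its place at most 2 rises and 2 falls per comparison are described, chosen in the same way, and IDs are printed for a single comparison.

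The planned selection of probe sets by symbol was replaced, after the data were seen, by all distinct probe sets: of those with identical values the first was kept (476 removed, 35080 left), and those with a mean log2 signal under the 25th percentile were removed, which left 26310. The selection by symbol (14953 probe sets) is given as an alternative.

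Comparisons were fitted as planned with limma 3.58.1 in R 4.3.3: a group-means model over all 20 arrays (lmFit, eBayes without trend, 10 residual degrees of freedom), Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. There were 16 comparisons fixed before the data were examined and 2 added after, the wax response in cKO skin and its difference from that in WT skin. The test of a difference between responses is the interaction contrast. Agreement between comparisons was described by Pearson and Spearman correlations across probe sets, only between comparisons without shared arrays. In place of gene lists, the probe sets changed at least 2-fold in the WT imiquimod or WT recovery comparison were tested with camera in comparisons without those arrays, with a preset correlation of 0.01 and with an estimated one, adjusted over the 40 tests. Errors are SD over the 2 arrays of a group, or the limma standard error where named.

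The model was tested on simulated data with the real row means and variances, 200 changed probe sets and 26310 in all. For the WT imiquimod comparison it found 49.3% of 1.5-fold, 80.6% of 2-fold and 98.5% of 4-fold changes, with 4 false calls. For the difference of responses these were 14.9%, 68.7% and 87.9%, with 8 false calls. For the mean genotype difference they were 98.5%, 98.5% and 100%, with 5 false calls.

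Alternatives fixed before the data were examined were pseudocounts of 1 and 64, quantile normalization, no filter, a filter at the 50th percentile, eBayes with trend and robust settings, only the arrays of a comparison, the replicate number as a block, and leaving out each array. The selection by symbol and leaving out the 4 injured recovery arrays were added later.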

Results

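Gene expression was measured in the dorsal epidermis of adult mice after 2 kinds of damage. Wax stripping is a physical injury that tears the outer layers off the skin. Imiquimod cream is an immune stimulant used to produce psoriasis-like inflammation. Each condition was sampled in Grhl3 wild-type (WT) mice and in Grhl3 conditional knockout (cKO) mice, in which Cre under the keratin 14 promoter acts in the epidermis. Grhl3 is a transcription factor of epidermal differentiation and barrier formation. The 20 arrays made 10 groups of 2, from 5 conditions: wax-stripped skin on day 4 (males), unaffected and injured areas on day 4 of the imiquimod experiment (females), and unaffected and injured areas of recovery skin on day 8 (males). The median probe-set signal per array lay between 169 and 200 intensity units, and the number of arrays per group is what limits the precision. Replicates are called biological in the labels.

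The values are reported by probe set, without gene names. The array has 35556 probe-set IDs, and the probe table pairs 21789 of them with 1 gene symbol, but the values did not bear that pairing out. Probe sets labelled as ribosomal protein genes, which are highly expressed in all tissues, had a median at percentile 55.4 of the mean signal (202 probe sets). Those labelled as olfactory receptors, which are expected to be silent in epidermis, had a median at percentile 54.5 (967 probe sets). Pairs of probe sets labelled with 1 symbol correlated over the arrays with a median r of 0.08 (8725 pairs), against 0.03 for random pairs. The IDs printed here are therefore labels of positions in the deposited table and not of genes, and the Grhl3 transcript itself could not be read. Levels, counts and comparisons between arrays do not need the names.

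The arrays separated first by injury. The first principal component held 49.9% of the variance over 26310 probe sets and placed all 8 arrays of unaffected skin between -52.7 and -32, and all 8 arrays of injured imiquimod and recovery skin between 23.5 and 60.9. The wax-stripped arrays lay in between, at -9.4 and -8 in WT mice and at 8.2 and 7.8 in cKO mice. Replicate arrays correlated at 0.978 to 0.992.

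**Figure D1:**
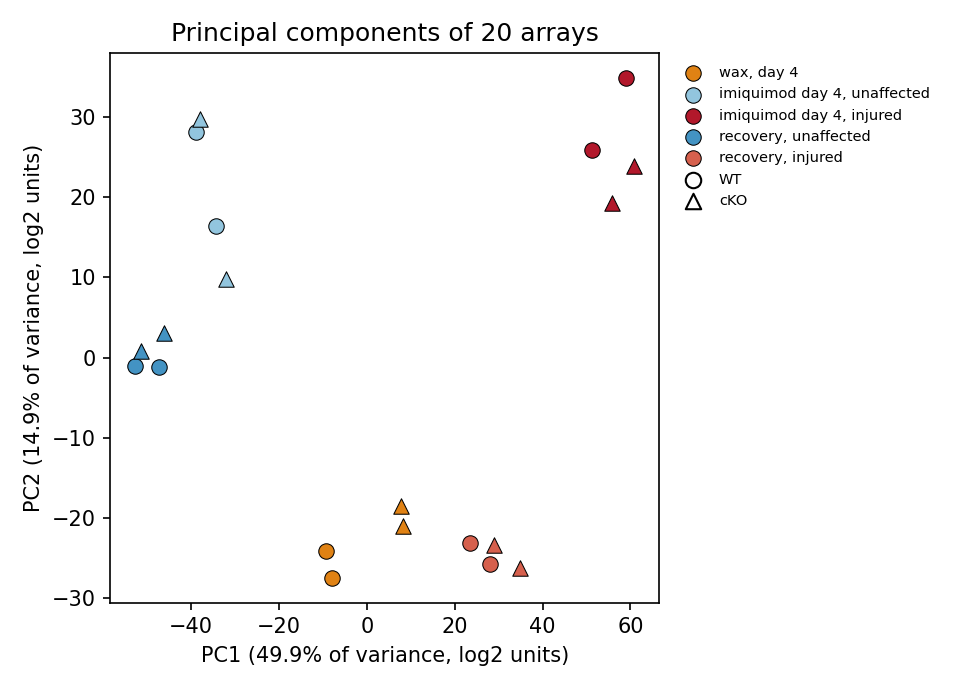
Each point is 1 of 20 arrays, placed by its scores on the first and second principal components of log2 signal over 26310 probe sets; colours give the condition, circles WT and triangles cKO. Injured imiquimod and recovery arrays lie at 23.5 or more on the first component, unaffected arrays at -32 or less, and wax-stripped arrays between, with cKO to the right of WT.

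The first comparison asked how wild-type epidermis responded to imiquimod by day 4. Of 26310 probe sets, 4239 rose and 5265 fell (limma, Benjamini-Hochberg adjusted p under 0.05), and 612 rose and 1389 fell by at least 2-fold. After quantile normalization 5236 rose and 5004 fell, so the balance of directions depends on the scaling. The probe set with the largest rise, 10486425, went from 19.7 ± 11 to 7430 ± 650 intensity units (SD, n = 2 each), a log2 change of 7.73 ± 0.21 (SE). The next, 10486562, went from 79.9 ± 13 to 20200 ± 5700 (SD, n = 2 each). The largest falls were in 10492890, from 3490 ± 530 to 34.1 ± 15 (SD, n = 2 each), and in 10561302, from 2660 ± 140 to 30.4 ± 8.9 (SD, n = 2 each). Their limma adjusted p values lay between 1.47e-10 and 2.05e-07. Being called and having no overlap of arrays between areas were conditions of their choice.

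The same comparison in cKO epidermis gave 4660 probe sets up and 4875 down, with 692 and 1247 changed at least 2-fold. More rose than fell after quantile normalization (5104 and 4677), with the filter at the 50th percentile (4387 and 4070), with the selection by symbol (3169 and 3068) and without unaffected cKO replicate 1 (4695 and 4386). The strongest rise went from 123 ± 33 to 49500 ± 400 intensity units (SD, n = 2 each), and the strongest fall from 3280 ± 660 to 76.6 ± 6.2 (SD, n = 2 each). Across probe sets, which are not independent replicates, the log2 changes of the 2 genotypes correlated at Pearson r = 0.92 and Spearman rho = 0.863. Of the 2001 probe sets that changed at least 2-fold in WT skin, 99.8% moved in the same direction in cKO skin and 1900 passed the test there, all in the same direction. A direct test of the difference between the cKO and WT responses called 1 probe set. It went from 1570 ± 370 to 3140 ± 140 in WT skin and from 1460 ± 2.1 to 9280 ± 370 in cKO skin (SD, n = 2 each; limma adjusted p = 0.0145). The call was lost (0) with only the arrays of the comparison, with the selection by symbol, without the injured recovery arrays and without injured WT replicate 2, and leaving out each array in turn gave 0 to 14. At an unadjusted p under 0.05 there were 1103, fewer than the share of 0.05 of 26310 probe sets that no difference at all would give. In simulated data with 200 changed probe sets, this test found 14.9% of 1.5-fold differences and 68.7% of 2-fold differences, so a small difference in response would often be missed. The adjusted threshold is stricter where fewer probe sets change, so these shares may be too high for the real data.

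Recovery skin was compared between injured and unaffected areas on day 8. In WT mice 4238 probe sets were higher and 4328 lower in the injured area, and in cKO mice 6174 were higher and 6924 lower, so the areas differed in both genotypes at this time. More were higher than lower with the filter at the 50th percentile, 4048 against 3301 in WT and 5565 against 3972 in cKO mice, and after quantile normalization in WT mice (4552 against 4171), so neither balance is fixed. The total of 8566 in WT skin became 5190 without injured replicate 1 and 5221 without unaffected replicate 1, and that of 13098 in cKO skin became 7473 without injured replicate 1 and 8723 without unaffected replicate 2. In the fit without injured cKO replicate 1 the WT total was 8150, above that of cKO skin, and in the other alternatives the cKO total was the higher one. A larger total is not a test of the genotypes, which is given below. As the next paragraph shows, these areas also differed in probe sets that follow the labelled sex elsewhere. The strong changes numbered 626 up and 644 down in WT skin and 858 up and 623 down in cKO skin. One of the largest rises in WT skin went from 8.63 ± 3 to 2640 ± 220 intensity units (SD, n = 2 each), and the same probe set in cKO skin went from 18.5 ± 16 to 3980 ± 370 (SD, n = 2 each). The responses of the 2 genotypes correlated at r = 0.859 (rho = 0.808) across probe sets. The test of the difference between them called 36 probe sets, 34 of them with the larger value in cKO. It called 17 without injured cKO replicate 1, 13 with the selection by symbol, and 2, 1 in each direction, with only the arrays of the comparison. The probe set with the largest difference among the 36 read 316 ± 1.3 in injured cKO and 38.4 ± 42 in injured WT skin. Unaffected cKO and WT skin read 44.6 ± 4.9 and 95.2 ± 21 (SD, n = 2 each). Its means in the wax and imiquimod groups were 292 to 378, so injured cKO recovery skin had their level and the other recovery groups lay below it. The probe set with the second largest difference was grouped alike, at 383 ± 47 in injured cKO and 77.7 ± 9.2 in injured WT skin. Unaffected cKO and WT recovery skin read 57.7 ± 6.9 and 131 ± 26 (SD, n = 2 each), and the wax and imiquimod means were 350 to 557. In these 2 a larger response to injury in cKO skin is therefore not shown. Whether others of the 36 are grouped alike was not tested. In one of the 2 of the 36 that were smaller in cKO, the injured area reached 7590 ± 1400 in WT mice and 1240 ± 150 in cKO mice, from 110 ± 9 and 108 ± 38 in unaffected skin (SD, n = 2 each, limma adjusted p = 0.00402).

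In 5 probe sets the injured recovery arrays did not follow their labelled sex. Each of these 5 parted the 8 arrays labelled female (all imiquimod day 4 skin) from the 8 labelled male in wax-stripped and unaffected recovery skin, by 3.67 to 6.74 on the log2 scale. All 4 injured recovery arrays, labelled male, had the level of the arrays labelled female. In WT skin, the clearest of them read 3660 ± 74 in unaffected and 15.9 ± 2.2 in injured recovery areas, against 12.9 ± 0.62 in injured imiquimod skin (SD, n = 2 each). A difference other than the injury between the injured and unaffected recovery areas is therefore not ruled out, and this applies to every comparison that sets one against the other, the counts of recovery skin above included.

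**Figure D2:**
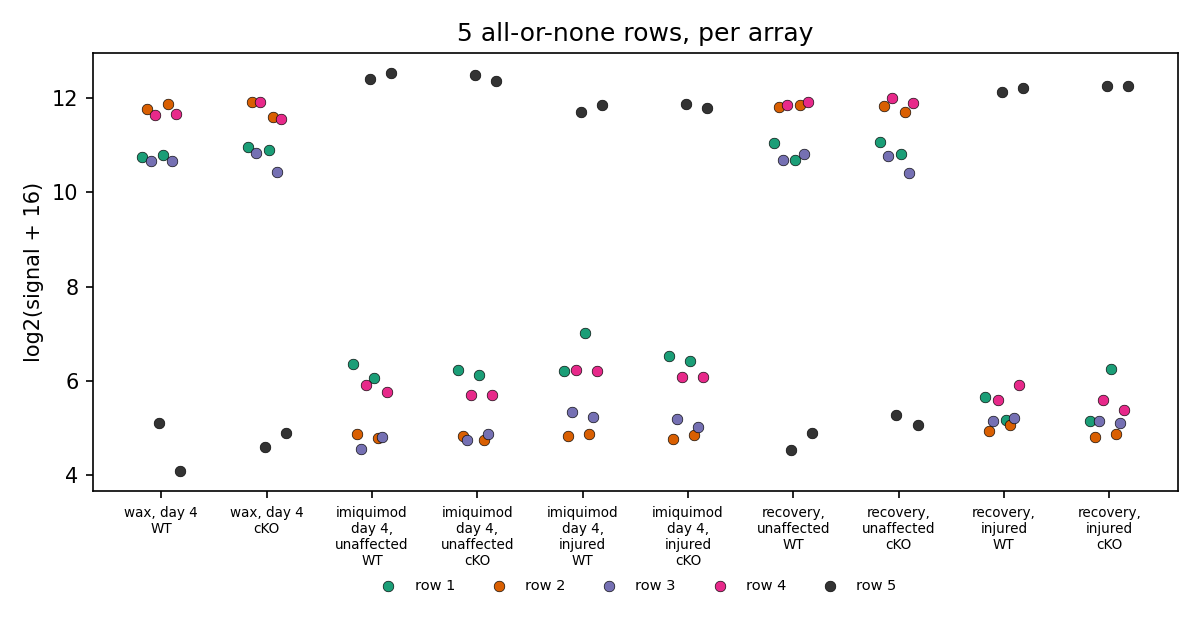
Log2(signal + 16) of the 5 probe sets that part arrays labelled female from arrays labelled male, on each of the 20 arrays, with 2 arrays per group side by side and each colour a probe set. The injured recovery arrays, labelled male, lie with the imiquimod arrays, labelled female, in all 5.

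In a further step, the imiquimod response on day 4 was compared with the difference in recovery skin. The probe sets that rose at least 2-fold with imiquimod in WT skin (612) had a median log2 difference of 1.14 in WT recovery skin, and 583 of them were higher in the injured area. The 1389 that fell had a median of -0.75, and 1231 of them were lower. Both sets stood apart from the other probe sets (camera, adjusted p = 3.6e-67 and 1.1e-38 with a preset correlation, adjusted p = 0.0065 and 0.00636 with an estimated correlation). Across all probe sets the 2 responses correlated at r = 0.68 (rho = 0.558) in WT and r = 0.67 (rho = 0.561) in cKO mice. The direct test of the day 4 minus the recovery response called 601 probe sets up and 1461 down in WT, and 1371 up and 1769 down in cKO mice (1357 each after quantile normalization). Among the probe sets these tests called, the largest difference in each direction was in a probe set on which injured recovery skin did not follow its labelled sex. Without injured recovery replicate 1, the count of 2062 in WT skin became 943 and that of 3140 in cKO skin became 915; 6 arrays each took the first to 943 to 1314, and 7 arrays each took the second to between 915 and 4914.

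Wax-stripped WT skin was compared with unaffected WT recovery skin, since no untouched skin of the wax experiment was analysed here. The 2 groups differ in day (4 against 8) and experiment as well as in treatment, and both are labelled male. The recovery mice had received imiquimod on another area, so wax and experiment cannot be told apart. Here 2850 probe sets were higher and 2926 lower after wax stripping, 387 and 172 of them by at least 2-fold. After quantile normalization 3042 were higher and 2455 lower, and with the filter at the 50th percentile 2853 and 2022. The largest rise was from 67.8 ± 29 to 2870 ± 24 intensity units, and the largest fall from 1880 ± 420 to 120 ± 36 (SD, n = 2 each). Leaving out any 1 of the 4 arrays compared took the total of 5776 to between 2105 and 3586. The imiquimod-raised set had a median log2 difference of 0.78 after wax stripping, with 538 of 612 higher, and the imiquimod-lowered set a median of -0.37, with 1110 of 1389 lower (camera adjusted p = 2.58e-48 and 8.57e-15 with a preset correlation, adjusted p = 0.0106 and 0.0433 with an estimated correlation). Across probe sets r was 0.473 and rho 0.423. The direct test of the wax minus the imiquimod response called 2438 probe sets up and 1239 down. Without wax-stripped WT replicate 2 it called 1508 up and 530 down. Labelled sex also differs in this test, male for the wax comparison and female for the imiquimod comparison. The 2 imiquimod-raised probe sets with the largest rise stayed low in wax-stripped WT skin, at 16.1 ± 3.7 and 102 ± 14 (SD, n = 2 each). The largest fall with imiquimod was from a level that wax-stripped skin kept, 5300 ± 72 (SD, n = 2). The second largest was also low after wax stripping, at 372 ± 150 against 3260 ± 110 in unaffected WT recovery skin (SD, n = 2 each).

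The comparison of genotypes after wax stripping asked whether Grhl3 loss changes skin after physical injury. In cKO mice 51 were higher and 20 lower than in WT mice, 43 and 8 of them by at least 2-fold. The largest difference was 8650 ± 1100 in cKO against 105 ± 24 in WT skin (SD, n = 2 each; limma adjusted p = 2.08e-05). The probe set with the second largest difference read 861 ± 110 against 16.1 ± 3.7 (SD, n = 2 each), and is the one with the largest imiquimod response in WT skin. A search for wide gaps between neighbouring arrays found 5 probe sets, with gaps of 3.09 to 4.87 on the log2 scale, that share 1 grouping. Wax-stripped cKO arrays lay above the gap with all injured imiquimod and recovery arrays, and wax-stripped WT arrays below it with all unaffected ones. The 2 probe sets with the largest genotype differences are among them, at 105 ± 24 and 16.1 ± 3.7 in wax-stripped WT against 117 ± 4.1 and 26.9 ± 1.9 in unaffected WT recovery skin. Another was raised below its gap, at 228 ± 15 against 8.63 ± 3 (SD, n = 2 each). Of the 612 imiquimod-raised probe sets 512 were higher in wax-stripped cKO than WT skin, with a median log2 difference of 0.23, and 44 passed the test, all higher. Of the 1389 imiquimod-lowered ones 1179 were lower, with a median of -0.19, and 8 passed the test, all lower (camera adjusted p = 2.22e-32 and 4.17e-26 with a preset correlation, adjusted p = 0.0299 and 0.0106 with an estimated correlation). These sets were chosen on other arrays, and the comparison itself was chosen after seeing the data. Across all probe sets the genotype difference correlated with the WT imiquimod response at r = 0.486 (rho = 0.403). A test of the wax response in cKO minus that in WT, also chosen after seeing the data, called 13 probe sets, all of them larger in cKO. The genotype count of 71 became 28 without WT replicate 2, 34 without cKO replicate 1 and 36 without WT replicate 1, and the 13 became 6 without WT replicate 2 and 8 without cKO replicate 1.

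**Figure D3:**
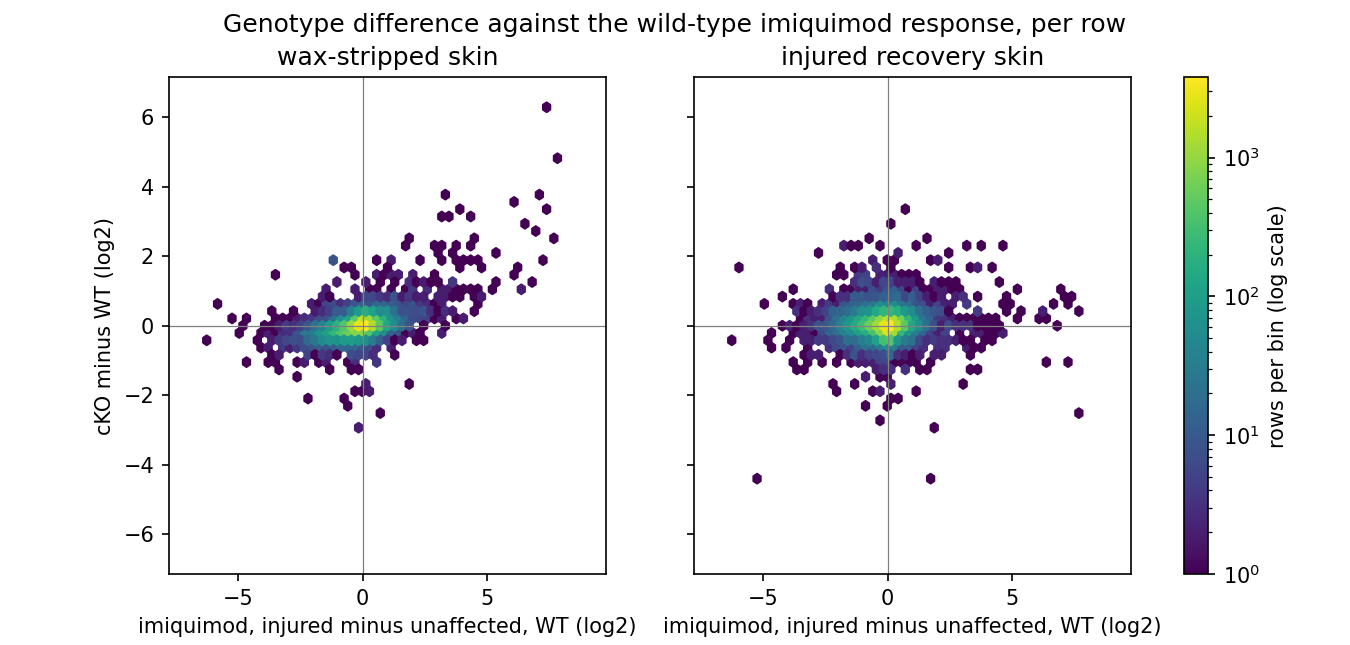
Each hexagon counts probe sets by the WT imiquimod response (x axis, log2) and the cKO minus WT difference (y axis, log2) in wax-stripped skin (left) and injured recovery skin (right), with a log colour scale. The cloud is tilted upward in wax-stripped skin (r = 0.486) and not in injured recovery skin (r = 0.056).

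Genotype was compared in the same way in the other conditions. In unaffected imiquimod skin limma called 2 probe sets, 1 higher and 1 lower in cKO (2555 at an unadjusted p under 0.05), 0 with only these arrays, and between 5 and 68 without any 1 of the 4. In unaffected recovery skin it called 0 (800 at an unadjusted p under 0.05). Without any difference a share of 0.05 of the 26310 probe sets would pass unadjusted, which is more than 800 and fewer than 2555. In injured imiquimod skin 20 were higher and 16 lower, and this count of 36 became 0 with only the arrays of the comparison, 3 without cKO replicate 1, 6 without cKO replicate 2 and 109 without WT replicate 1; without WT replicate 2 more were lower (25) than higher (19). One of those higher in cKO read 4910 ± 380 against 975 ± 89 in WT, and one of those lower read 828 ± 88 against 2100 ± 92 (SD, n = 2 each). In injured recovery skin 190 were higher and 73 lower, and the total of 263 became 62 to 143 without any 1 of the 4 arrays and 43 with only these arrays. After quantile normalization the split there was 146 higher and 94 lower. The imiquimod-raised set had a median genotype difference of 0.01 in unaffected and 0.1 in injured recovery skin. In the latter the set's camera adjusted p was 0.000137 with a preset correlation and adjusted p = 0.526 with an estimated correlation. The genotype differences of different conditions, from separate arrays, correlated across probe sets at r between -0.019 and 0.4 (10 pairs, median 0.056). These values were not evenly spread. Between unaffected and injured imiquimod skin r was 0.4, and injured recovery skin correlated with these at 0.274 and 0.341. Wax-stripped and unaffected recovery skin correlated at 0.356. All other pairs lay between -0.019 and 0.066. By rank these other pairs tended weakly the opposite way, with Spearman rho between -0.159 and -0.09, against 0.315 to 0.436 in the pairs named before. The 5 probe sets that part the labelled sexes divide the conditions as these correlations do, but their choice fixed the side of every condition except injured recovery skin. Why the genotype differences follow this division was not tested.

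**Figure D4:**
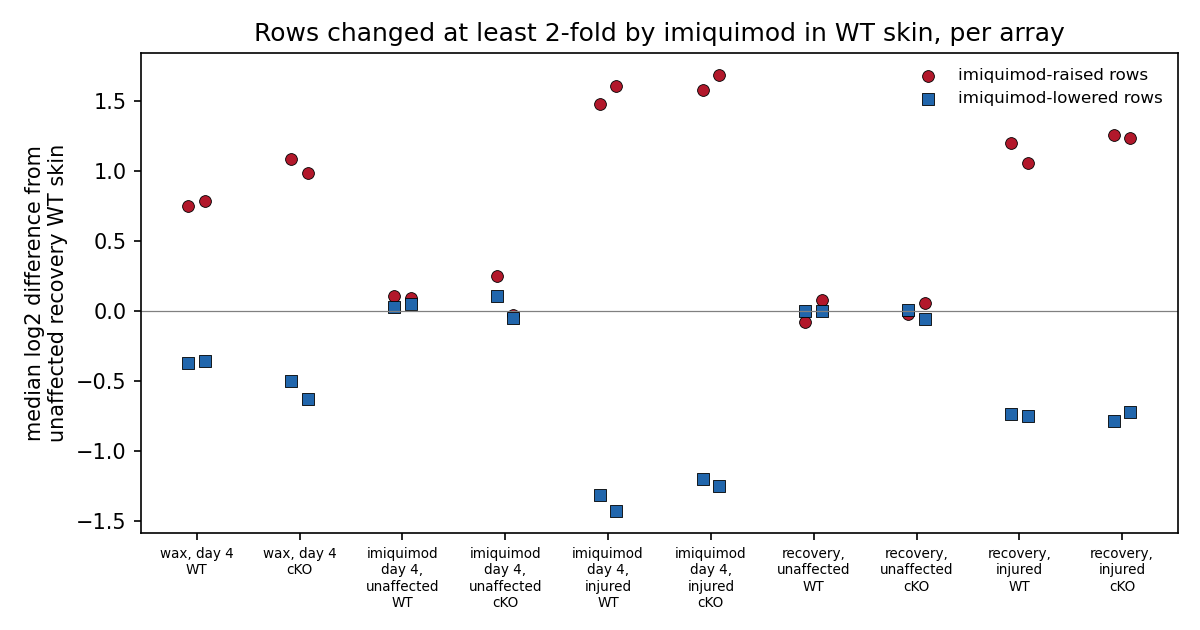
Median log2 difference of the 612 imiquimod-raised (circles) and 1389 imiquimod-lowered (squares) probe sets from the mean of unaffected WT recovery skin, on each of 20 arrays. The sets were chosen on the WT imiquimod arrays; wax-stripped cKO arrays lie at 1.09 and 0.99 for the raised set, against 0.75 and 0.79 in wax-stripped WT skin.

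Averaged over the 5 conditions (10 arrays per genotype), 239 probe sets were higher and 152 lower in cKO epidermis. After quantile normalization they were 198 and 202. The median size of the called differences was 0.31 on the log2 scale. The largest mean rise was of 1.71 ± 0.15 (SE), in a probe set at 1130 ± 260 in cKO against 103 ± 4.4 in WT wax-stripped skin (SD, n = 2 each) and at 122 ± 11 against 124 ± 29 in unaffected recovery skin. The largest mean fall, -3.45 ± 0.46 (SE), was in a probe set at 1200 ± 440 in WT and 5.95 ± 8.4 in cKO injured imiquimod skin (SD, n = 2 each; limma adjusted p = 0.00233). On 65 probe sets both cKO arrays were higher than both WT arrays in every condition, and on 42 lower, where chance ordering of unrelated arrays gives 3.4 each. That number holds only if the 5 conditions are independent. Areas of 1 experiment may come from the same mice, which would raise it. Without the injured recovery arrays the mean over 4 conditions called 89 probe sets, and over 5 conditions leaving out 1 array gave 184 to 502.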

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

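Some of the tests of explanations here were set before their result was seen. These were the correlations after quantile normalization, without 1 wax array and of replicate differences. Both tests of pairs of probe sets with 1 symbol, the slopes on unaffected skin and the splits of genotype were also set before. The other tests of explanations were chosen only after the result was seen. Differences between responses were tested directly. These comparisons were fixed before the data were examined, except that of the wax responses of the genotypes. The imiquimod response differed between cKO and WT skin in 1 probe set and the recovery response in 36. The day 4 and recovery responses differed in 2062 probe sets in WT and 3140 in cKO mice. The wax and the imiquimod responses of WT skin differed in 3677, and the wax response differed between genotypes in 13.

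The first pattern concerns the names: probe sets labelled as 1 gene did not move together. If the labels had been displaced from their values, pairs with 1 symbol would correlate hardly more than random pairs, and their median exceeded that of random pairs by 0.05. A displacement of the labels is consistent with this value. Noisy arrays would also hide such pairs. Among the 1071 pairs (153 symbols) whose probe sets repeated their profile over the 10 groups between replicates (r over 0.8), the median exceeded that of random pairs chosen in the same way by 0.094, with a bootstrap SE of 0.079, which does not settle whether noise hides them. Noise in the changes does not bear on the levels of ribosomal protein and olfactory receptor labels, which lay at percentiles 55.4 and 54.5. How a displacement arose was not tested, and no biological explanation was tested.

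The second pattern is the injured recovery skin. On all 5 probe sets that part arrays labelled female from arrays labelled male, the 4 injured recovery arrays lay on the female side, and on 0 they lay on the male side. The values are what a wrong sex label of the injured recovery arrays would give. Of the 5 probe sets, 4 were higher in arrays labelled male and 1 in arrays labelled female. An effect of the injury in recovery skin would have to lower the 4 and raise the 1, each to near the level of arrays labelled female. The comparison of unaffected arrays cannot decide this. Unaffected imiquimod and unaffected recovery arrays differed by at least 4.71 on these probe sets, but the way they were chosen fixes such a difference. Also, sex and experiment coincide in the other arrays, so a shared source other than sex may do the same. Whether such a difference runs through the rest of the recovery response cannot be told apart from the response: with the imiquimod response in the regression, the slope on the difference of unaffected arrays was 0.09 higher for recovery than for wax in cKO skin, and the excess was 0 in WT skin.

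The third pattern is the shift of wax-stripped cKO skin towards the imiquimod response (r = 0.486). The scaling of the arrays is argued against by r = 0.488 after quantile normalization, and a single deviating array by the lowest value without 1 wax array, 0.405. If animals of any genotype differed this way, replicates would too. In the 8 other groups the strongest correlation of a replicate difference with the imiquimod response was 0.126 in size. In the wax groups the sizes were 0.014 and 0.028. These values argue against such animals but do not exclude them. Some of the 8 groups are unaffected skin, without an injury response that could vary, and each wax group gives a single replicate difference. A shift as strong in every condition from loss of Grhl3 is argued against by the correlations in injured and unaffected recovery skin, 0.056 and 0.062 with leave-one-out errors of 0.077 and 0.113, against 0.486 with an error of 0.097. A weaker shift in the other conditions is not excluded. The genotype differences of injured and unaffected imiquimod skin correlated with the WT recovery response at r = 0.159 (rho = 0.253) and r = 0.084 (rho = 0.172), with errors of 0.088 and 0.197, so that r exceeded its error in 1 of these 4 conditions. The genotype difference after wax stripping correlated with that of unaffected recovery skin at r = 0.356 (rho = 0.325), but with those of injured recovery, unaffected imiquimod and injured imiquimod skin at r = 0.066 (rho = -0.091), r = 0.046 (rho = -0.09) and r = -0.007 (rho = -0.159). An effect of Grhl3 loss after wax stripping alone and a weaker one in other conditions as well remain open as hypotheses. So do a difference in handling or timing between the 2 wax groups and one between their animals, with 2 arrays per group.

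The mean genotype difference over 5 conditions called 391 probe sets. Of 100 splits of the arrays within conditions, the real one included, 1 gave as many, and the highest other gave 164. This argues against a random assignment of arrays as the source of the count. The splits treat arrays as independent, so other differences between WT and cKO animals are not excluded.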

How the results depend on the processing

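Of 296 values recomputed under settings other than leaving out 1 array, 258 stayed within 1.5 times of a count, on their side of a threshold or within the leave-one-out error of a correlation, and 38 did not. Among the probe sets, only the 4 of the WT imiquimod response were recomputed (2 with the selection by symbol); none of these changes and none of the recomputed correlations over 0.1 in size changed sign. The split of a count by direction was not part of this. All values kept under pseudocounts of 1 and 64. The mean over probe sets of a gene, the Grhl3 level, the fixed lists and the markers were not run, since the labels do not name the values. The cause was not tested unless given here. With 2 arrays per group, differences under 2-fold are limited by the number of arrays.

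The balance of directions turned in several counts. After quantile normalization more rose than fell with imiquimod in WT (5236 and 5004) and cKO (5104 and 4677) skin, in WT recovery (4552 and 4171) and after wax stripping in WT skin (3042 and 2455), and the mean genotype difference became 198 higher and 202 lower. With the filter at the 50th percentile it turned for imiquimod in cKO skin (4387 and 4070), recovery in WT (4048 and 3301) and cKO (5565 and 3972) skin and wax stripping in WT skin (2853 and 2022). Trend and robust settings turned recovery (4392 and 4247) and wax stripping (3023 and 2783) in WT skin.

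The count for genotype in unaffected imiquimod skin (2) became 4 with quantile normalization, 4 without a filter, 1 with the filter at the 50th percentile and 9 without the injured recovery arrays. Without a filter the mean genotype difference called 260. In unaffected recovery skin (0) genotype called 1 with the filter at the 50th percentile, 1 with trend and robust settings and 1 without the injured recovery arrays. The filter at the 50th percentile gave r = 0.54 between the wax and imiquimod responses of WT skin. Trend and robust settings gave 109 for genotype after wax stripping.

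With only the arrays of a comparison, which leaves 2 or 4 residual degrees of freedom, the imiquimod response called 6105 in WT and 5882 in cKO skin and its difference 0, the difference of recovery responses 2, the day 4 minus recovery response 715 in WT and 1340 in cKO skin, genotype 0 in unaffected and 0 in injured imiquimod skin and 43 in injured recovery skin, the wax response in cKO skin 3749 and its difference between genotypes 7.

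Same-numbered arrays did not deviate together in a common way: over 9 pairs of groups the correlation of replicate differences lay between -0.259 and 0.286. Of these pairs 3 were above 0.1, all between genotypes of 1 condition. The numbers were therefore not taken to pair the arrays, though a pairing in some groups is not excluded. With the replicate block the difference of imiquimod responses called 0, that of recovery responses 3, the day 4 minus recovery response 726 in WT and 1057 in cKO skin, and genotype in unaffected imiquimod skin 1; the other 13 counts stayed within 1.5 times.

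The selection by symbol tests fewer probe sets (14953) and called 6246 for the imiquimod response in WT, 6237 in cKO skin and 0 for its difference, 5599 and 8123 for recovery with 13 for its difference, 1 for genotype in unaffected imiquimod and 1 in unaffected recovery skin, and 6 for the difference of wax responses. Without the injured recovery arrays, added after seeing the data, the difference of imiquimod responses called 0, genotype in injured imiquimod skin 23, and the mean genotype difference 89.

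Leaving out each of the 20 arrays in turn, which also lowers the number of arrays, left the imiquimod response within 1.5 times (7350 to 9867 in WT and 6755 to 9590 in cKO skin). The correlation of WT and cKO responses ranged from 0.864 to 0.922 for imiquimod and from 0.803 to 0.876 for recovery, that of day 4 and recovery from 0.635 to 0.691 in WT and from 0.591 to 0.705 in cKO skin, and that of wax and imiquimod in WT skin from 0.428 to 0.494. The other counts ranged as follows. The difference of imiquimod responses called 0 to 14 and that of recovery responses 17 to 41. The recovery response called 5190 to 9163 in WT and 7473 to 13856 in cKO skin, and the day 4 minus recovery response 943 to 2475 and 915 to 4914. The wax response called 2105 to 6569 in WT and 3772 to 6943 in cKO skin, its difference from imiquimod 2038 to 4273 and its difference between genotypes 6 to 19. Genotype called 28 to 80 after wax stripping, 2 to 68 in unaffected and 3 to 109 in injured imiquimod skin, 0 to 7 in unaffected and 62 to 284 in injured recovery skin, and 184 to 502 over 5 conditions.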

Other observations

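The probe sets described here were chosen after the data were seen. On 3 probe sets, with gaps of 3.21 to 3.84 on the log2 scale, all 12 arrays of wax-stripped, injured imiquimod and injured recovery skin lay above all 8 arrays of unaffected skin, in both genotypes. One of them read 2870 ± 24 after wax stripping, 9070 ± 56 after imiquimod and 8170 ± 53 in injured recovery skin of WT mice, and 67.8 ± 29 in unaffected WT recovery skin (SD, n = 2 each).

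The probe set with the largest mean fall in cKO epidermis varied between cKO arrays. It read 892 to 5220 intensity units on the 10 WT arrays and from near 0 to 2000 on the 10 cKO arrays, 5 of which were under 100. The probe set with the second largest fall followed it over the 20 arrays (r = 0.984 on the log2 scale, both chosen after their values were seen). The cKO arrays of recovery skin differed most: replicate 1 read 336 and replicate 2 read 2000 in the unaffected area, and 52.6 and 1180 in the injured area.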
